A study of Mus musculus with 10 samples.

How the data were processed

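Total RNA of 10 aortas was hybridized to Affymetrix Mouse Gene 2.0 ST arrays, per the labels' protocols. The sample titles give 2 groups of 5 biological replicates, one lacking ApoE alone and the other lacking IL-17 as well, called the double knockout. The deposited values are 1 number per probe set and array on a log2 scale, and per the submitters' processing notes limma was used, with no version or role given. That the base of the log is 2 was inferred from the range of the values, since it is not stated. The methods of background correction, normalization and summarization are not given in the sources used here. The values were not centred per gene. Array medians over all probe sets ran from 5.76 to 6.03, and upper quartiles lay closer together between the groups than lower ones.

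The protocol text of the ApoE knockout samples describes a set of animals that includes wild-type and ApoE/caspase-1 deficient mice and makes no mention of IL-17, and it differs from the text of the double knockout samples. Scan dates and batches are not given in the sources used here. How the aortas were rinsed or cleaned of surrounding tissue, and the time of day at collection, are likewise not given.

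Probe sets were named through the platform annotation. Of 41345 probe sets, 23521 had 1 gene symbol, 1814 had several and were not named, and 16010 are unnamed here. Of the symbols, 23328 were found by gene identifier in the reference gene table of assembly GRCm38.p6, 193 were not and kept the annotation's name, and 0 had to be updated. That table served for names and the order of genes along the chromosome, with no coordinates. For the 1082 genes with several probe sets, the one with the highest mean over the 10 arrays was used, which left 22180 genes. In 24 genes the called probe sets disagreed in direction. No filter on dim probe sets was applied and no further normalization was done.

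Genes were tested with lmFit and eBayes of limma 3.58.1 in R 4.3.3, with group as the only term, two-sided, and Benjamini-Hochberg adjustment over all genes at a threshold of 0.05. An adjusted p printed for a gene comes from this fit, effects are double knockout minus ApoE knockout, and SE is the standard error on the log2 scale. Gene lists were tested with camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the 42 lists with at least 5 measured members out of 43. An estimated correlation, fry and ranks were alternatives. Camera compares a list with all other genes, while fry asks whether a list's genes move on balance one way. A list score is the mean log2 value of its genes in an array, and scores and array measures were compared with an exact permutation test over all 252 assignments, two-sided, for which the smallest possible p is 0.0079. Figures were drawn with matplotlib 3.10.9.

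The groups, the main test, the lists and the rule for named genes were fixed before the data were examined. The lists covered IL-17 responses and the IL-17 family, endothelial activation, chemokines, p38 and AP-1, immediate early genes, the inflammasome, interferon, class II presentation, complement, foam cells, cholesterol, fatty acid synthesis and oxidation, oxidative phosphorylation, glycolysis, the clock, the unfolded protein and heat shock responses, oxidative stress, the cell cycle, matrix, matrix proteases, ribosomal proteins and mitochondrially encoded genes. A further 18 lists held markers of smooth muscle, endothelium, fibroblasts, macrophages, T cells, B cells, plasma cells, neutrophils, dendritic cells, mast cells, white and brown adipocytes, skeletal and cardiac muscle, Schwann cells, mesothelium, chondrocytes and erythroid cells. Named genes are the targeted genes, the 12 largest increases and 12 largest decreases among called genes whose groups do not overlap (predicted genes, clones and receptor genes skipped), up to 4 members with the smallest p of each called list, up to 2 of each other list, and up to 6 called genes near Il17a. The receptor gene level, the red cell, platelet and clock arm lists and the exact test of list scores were added after the data were seen. Genes counted as at the level of the receptor genes have both group means below 5.78. Where 1 group mean alone lies below it, background may limit the fold, which is then read as a lower bound. The background of single probe sets is not known here.

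Alternatives covered filters on dim genes, quantile normalization, centring of arrays, the probe set rule, the prior, array weights, the replicate number as a block, covariates, thresholds, Welch's test per gene and leaving out each array in turn. The code was tested on simulated data for the comparison of double knockout with ApoE knockout with 22180 genes, of which 200 were changed. It recovered 90% of the genes changed by 1 on the log2 scale and 99% of those changed by 2, all with the right sign, and made 13 false calls. It recovered 3 of 3 shifted lists and called 0 of the 34 lists that share no member with them. The simulated genes varied independently of one another, so this does not show how often lists of correlated genes are called falsely.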

Results

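The data are expression profiles of whole aortas from 10 male mice, measured on Affymetrix Mouse Gene 2.0 ST arrays. Apolipoprotein E (ApoE) clears lipoprotein remnants from plasma, and mice without it become hyperlipidemic and develop atherosclerosis. One group of 5 lacked ApoE alone, and the other group of 5 lacked both ApoE and the cytokine IL-17. All mice ate a high fat diet for 3 weeks from 8 weeks of age, and aortas were taken at 11 weeks, an early stage of hyperlipidemia. The comparison asks how the loss of IL-17 alters gene expression in the ApoE-deficient aorta. Each array gave values for 41345 probe sets, from which 22180 genes were tested, and the number of arrays limits the precision. The correlation between arrays, across genes, ran from 0.980 to 0.987 within the ApoE knockout group, from 0.972 to 0.988 within the double knockout group and from 0.964 to 0.980 between them.

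The targeted genes were examined first. Il17a, which encodes IL-17A, had a mean log2 value of 4.41 ± 0.14 in the ApoE knockout aortas and 4.66 ± 0.17 in the double knockout aortas (SD, n = 5 per group). The difference of 0.25 (SE 0.10, limma adjusted p = 0.073, 5 arrays per group) turned to -0.02 after quantile normalization. These values lie below 5.78, the 95th percentile of the mean levels of 1429 olfactory, vomeronasal and taste receptor genes, called receptor genes from here on, which the aorta is not known to use. Since the position of the probes relative to the deletion is not given in the sources used here, Il17a checks nothing about the genotype labels. Il17f, the neighboring family member, was 1.44-fold higher in the double knockout (log2 change 0.52, SE 0.11, adjusted p = 0.0064), a call that was lost after quantile normalization (0.35, adjusted p = 0.056). Apoe, deleted in both groups, ranged from 6.07 to 6.47 in the ApoE knockout and from 6.83 to 7.26 in the double knockout aortas, a rise of 0.67 (SE 0.10, adjusted p = 0.0011).

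The largest decreases in the double knockout aortas included several genes of red blood cells. Hbq1a, a hemoglobin theta chain, was at least 16.7-fold lower (9.84 ± 0.91 against 5.79 ± 0.40, mean log2 value ± SD, n = 5 per group). Slc4a1, the band 3 anion exchanger of the red cell membrane, was 8.41-fold lower (10.29 ± 0.28 against 7.22 ± 0.40). Car2, a carbonic anhydrase abundant in red cells, was 10.1-fold lower, and Slc25a37, the mitochondrial iron importer mitoferrin 1, was 7.68-fold lower. Apol11b, an apolipoprotein L family member, was at least 20.4-fold lower (10.09 ± 0.45 against 5.74 ± 0.40). In 4 of the 5 double knockout aortas both Hbq1a and Apol11b lay below 5.78, the level of the receptor genes. Background may therefore limit these folds, and they are read as lower bounds. The median of the receptor genes per array was lower, on average 3.65 in the ApoE knockout and 3.96 in the double knockout. Limma adjusted p-values of these 5 genes lay between 2.5e-06 and 7.2e-05, and every double knockout aorta was below every ApoE knockout aorta.

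The other 7 of the 12 largest decreases were Cyp4b1-ps2 (15.3-fold), Ctse (6.46-fold), Mkrn1 (6.11-fold), Fam220a (5.92-fold), Rsad2 (5.70-fold), Isg20 (5.49-fold) and Trbv13-2 (5.47-fold). Ctse encodes the protease cathepsin E, and Rsad2 and Isg20 are antiviral genes induced by interferon. Cyp4b1-ps2 is a pseudogene and Trbv13-2 a variable segment of the T cell receptor, so signal shared with related sequences leaves these values uncertain. Their double knockout means, 5.01 and 5.06, also lay below the level of the receptor genes, so these 2 folds and their ranks may depend on the background.

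Among the 12 largest increases, Dpep2, a membrane dipeptidase, lay well above the level of the receptor genes and was 3.28-fold higher (7.76 ± 0.37 against 9.48 ± 0.22, n = 5 per group, adjusted p = 1e-04). Bend6 rose 2.56-fold (adjusted p = 6.1e-06), and Wif1, a secreted inhibitor of Wnt signaling, rose 2.27-fold (adjusted p = 0.00046). The inducible heat shock genes Hspa1b and Hspa1a rose 2.81-fold and 2.54-fold, though these near-identical copies may share signal. Phxr4 rose 2.40-fold. The largest increase, 5.62-fold, belonged to Rnu3a, a small nucleolar RNA gene with several copies, and Morf4l1-ps1, a pseudogene, rose 3.24-fold, so both values are uncertain. The remaining 4, Cypt14, Rsph4a, Ssxb8 and Lyzl4os, rose by 2.32-fold to 3.08-fold from means of 3.01 to 4.62 in the ApoE knockout, within the range of the receptor genes.

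**Figure D1:**
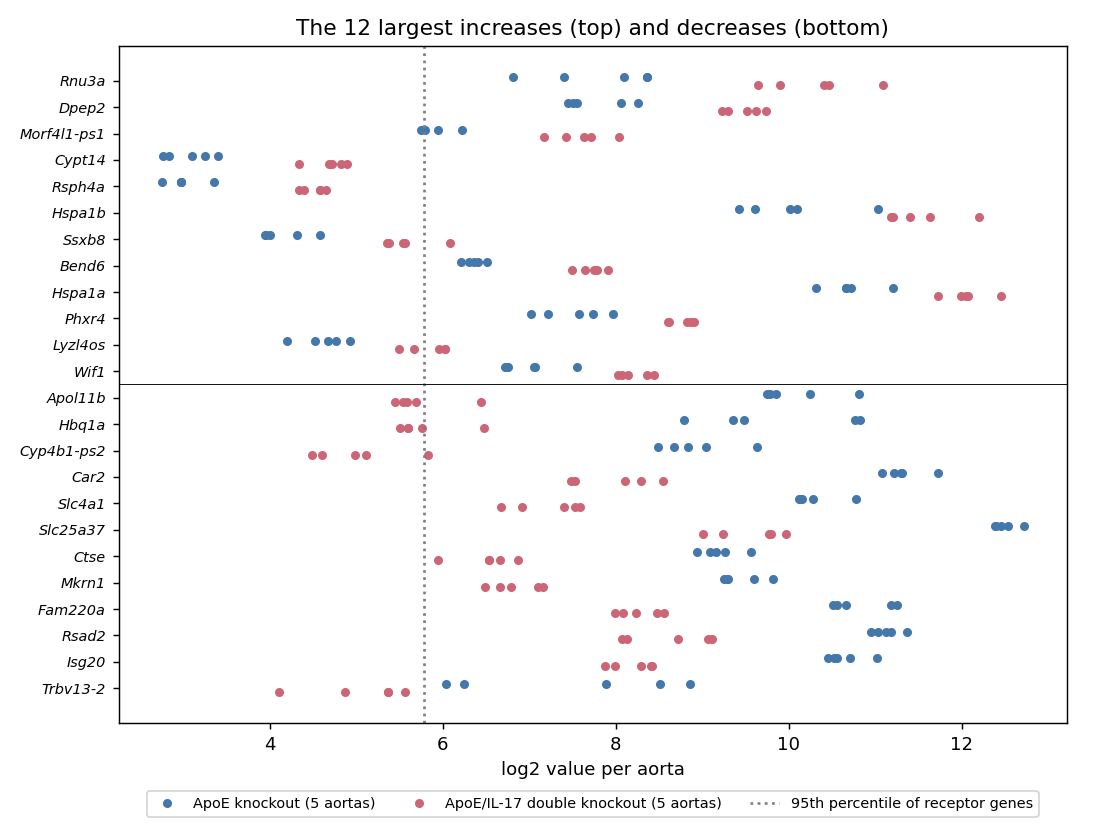
Log2 value (horizontal axis) of the 12 genes with the largest increase and the 12 with the largest decrease, one row per gene, with a point for each of the 5 ApoE knockout (blue) and 5 double knockout (red) aortas. The groups do not overlap in any row, as the choice of genes required, and Cypt14, Rsph4a and Ssxb8 have both group means below the dotted line at 5.78, the 95th percentile of the receptor genes.

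Of the 22180 genes tested with limma, 6721 passed an adjusted p of 0.05, of which 5050 (75.1%) were higher and 1671 lower in the double knockout. A change of at least 1.5-fold was seen in 1640 of them (1195 higher, 445 lower) and of at least 2-fold in 272 (109 higher, 163 lower). The groups did not overlap for 4525 genes, of which 4279 passed, where chance gives a share of 0.0079. The split depended on the normalization: after each array was centred on its median, 60.9% of 5877 called genes were higher, and after quantile normalization 44.4% of 4461. No scan date or batch is given, so batch and genotype cannot be told apart if the groups were run separately. The 2 groups carry different protocol texts and were registered under separate ranges of sample numbers, which leaves separate runs open.

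Dim genes made up much of the excess of increases. Among the 8872 genes in the lowest 40% by mean level, 3187 were higher and 207 lower, with a median log2 change of 0.25. Among the other 13308 genes, 1863 were higher and 1464 lower, with a median of 0.01. Receptor genes moved in the same direction: 425 of 1429 were higher and 12 lower, with a median of 0.29. The lower quartile of each array's values over all probe sets was 4.52 ± 0.02 in the ApoE knockout and 4.78 ± 0.04 in the double knockout (SD, n = 5, exact permutation p = 0.0079, adjusted p = 0.019 over 24 measures), while the upper quartiles were 7.59 ± 0.02 and 7.63 ± 0.03 (exact permutation p = 0.079). The median log2 change of all genes was 0.10 as deposited and -0.02 after quantile normalization, and a list's change is read against that of all other genes.

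**Figure D2:**
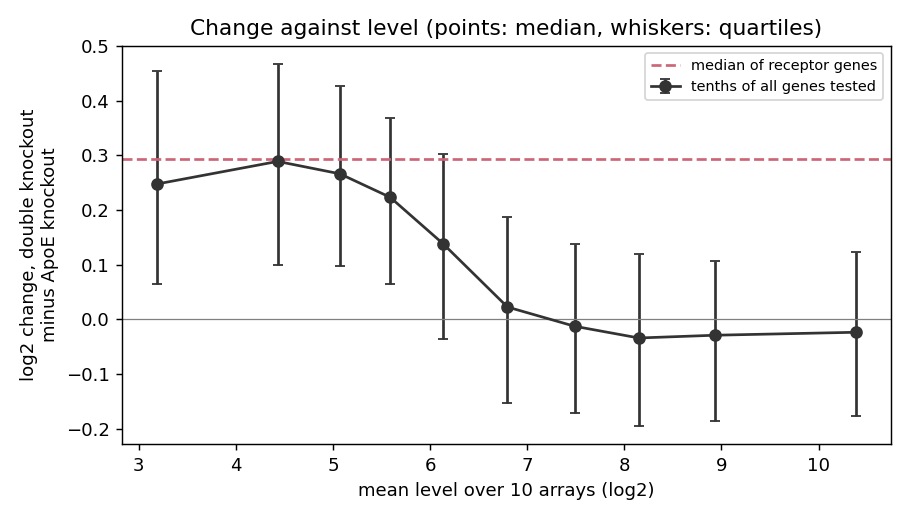
Median log2 change of the genes, double knockout minus ApoE knockout (vertical axis), against their mean level over the 10 arrays (log2, horizontal axis), for 10 equal groups of genes ordered by level, with whiskers from the lower to the upper quartile. The median lies between 0.22 and 0.29 in the 4 dimmest groups, close to the receptor genes (dashed line, 0.29), and between -0.03 and 0.02 in the 5 brightest.

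Genes of lymphocytes and granulocytes were lower in the double knockout aortas. In the B cell list, 7 of 13 genes fell and none rose, among them both chains of the B cell receptor signaling unit, Cd79b (3.37-fold lower, log2 SE 0.16) and Cd79a (2.64-fold, SE 0.15), the surface marker Ms4a1 (2.49-fold, SE 0.16) and the IgM receptor Fcmr (2.53-fold, SE 0.15). In the T cell list, 6 of 12 fell, including the CD3 chains Cd3g (4.60-fold, SE 0.51) and Cd3d (2.05-fold, SE 0.27) and the lymph node homing receptor Ccr7 (2.29-fold, SE 0.17). In the neutrophil list, 7 of 15 fell, such as Retnlg (3.81-fold, SE 0.39), the calcium-binding protein gene S100a8 (3.76-fold, SE 0.41) and the receptor gene Csf3r (2.09-fold, SE 0.21), while Mpo rose 1.53-fold within the range of the receptor genes. In the mast cell list, 7 of 11 fell, including the proteases Mcpt4 (3.37-fold, SE 0.29) and Tpsb2 (2.27-fold, SE 0.23), and Ms4a2 rose at the level of the receptor genes, a call lost after quantile normalization (adjusted p = 0.057). The double knockout means of Ms4a1 (5.54), Fcmr (5.64), Cd3d (5.53) and Retnlg (5.52) lay below 5.78, the level of the receptor genes. Their folds are therefore read as lower bounds.

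Adjusted over the list alone, 9 B cell, 11 T cell, 9 neutrophil and 7 mast cell genes were lower, and 1 neutrophil and 1 mast cell gene higher. Median log2 changes were -0.53 for B cells, -1.12 for T cells, -0.98 for neutrophils and -0.71 for mast cells. By camera with a preset correlation the adjusted p-values were 2.6e-08, 3.4e-06, 7.1e-05 and 6.1e-05. For each of these 4 lists it was adjusted p = 0.51 with an estimated correlation. The mean level of the B cell genes was 6.68 ± 0.29 in the ApoE knockout and 5.93 ± 0.16 in the double knockout (SD, n = 5, exact permutation p = 0.0079, adjusted p = 0.048 over the 42 lists). The neutrophil and mast cell scores reached the same exact p, the smallest that 5 against 5 arrays can give, and the T cell score did not pass (exact permutation p = 0.048, adjusted p = 0.15). ApoE knockout replicates 1 (7.13) and 5 (6.73) had T cell scores within the double knockout range (6.24 to 7.17).

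Red cell genes were lower in the double knockout too. The fixed erythroid list had only 3 measured members, too few to test, of which Slc4a1 and Epb42 (at least 2.29-fold lower, to a mean of 5.67 below the level of the receptor genes, adjusted p = 0.00086) fell and Bpgm did not pass (log2 change -0.87, SE 0.52, adjusted p = 0.22).

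**Figure D3:**
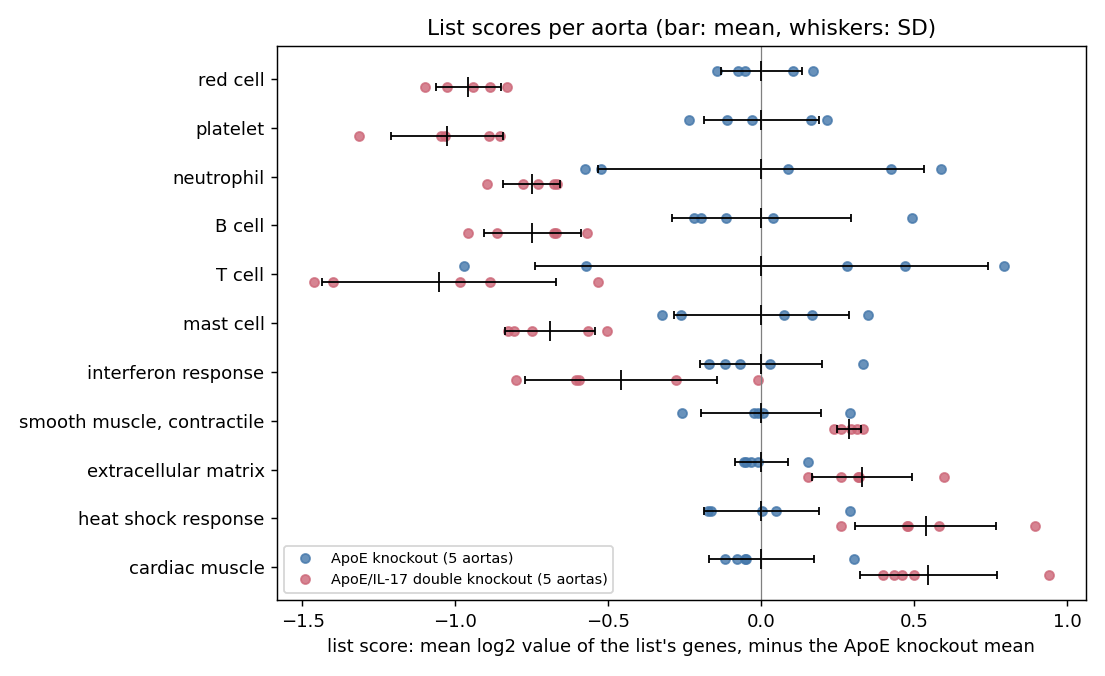
Mean log2 value of the genes of 11 lists in each aorta, minus the ApoE knockout mean (horizontal axis), one row per list, with points for the 5 ApoE knockout (blue) and 5 double knockout (red) aortas, a bar at the group mean and whiskers of 1 SD. The double knockout means lie 0.75 below for neutrophil and B cell genes, 0.46 below for interferon response genes and 0.33 above for extracellular matrix genes; the points of the groups overlap for T cell, interferon, smooth muscle and heat shock genes, and the red cell and platelet lists were put together after the data were seen.

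Several interferon response genes were lower in the double knockout. Rsad2, whose product is the antiviral protein viperin, was lower by 2.51 on the log2 scale (SE 0.20), a gap wider than either group's spread (11.13 ± 0.16 against 8.62 ± 0.50, SD, n = 5). In the ApoE knockout, Rsad2 ordered the 5 aortas as the red cell gene Slc25a37 did. Both were lowest in replicate 3 (10.95 and 12.38) and highest in replicate 2 (11.37 and 12.72). In the double knockout both were highest in replicate 1 (9.11 and 9.97), but lowest in different replicates, and Irf7 was highest in replicate 2 (8.32). Other red cell genes did not share the ApoE knockout order of Rsad2. Slc4a1 and Hbq1a were lowest there in replicate 1 (10.12 and 8.79), and Hbq1a was highest in replicate 5 (10.83). Car2 shared the lowest and the highest replicate with Rsad2, but not the order between them. The source of the Rsad2 change was not tested. Irf7, the main transcription factor of the type I interferon response, was 2.84-fold lower (SE 0.22), Oas3 was 2.10-fold lower (SE 0.17) and Ifit1 1.89-fold lower (SE 0.21). In all, 7 of 26 genes of the list fell, 1 rose and 18 did not pass, with the same counts adjusted over the list alone (median log2 change -0.37, camera adjusted p = 1e-05, adjusted p = 0.51 with an estimated correlation). The list's score did not pass after adjustment (7.38 ± 0.20 against 6.92 ± 0.31, SD, n = 5, exact permutation p = 0.040, adjusted p = 0.14), and double knockout replicate 2, at 7.37, lay within the range of the ApoE knockout. Macrophage markers were lower beside this list (median -0.31), as were the class II and leukocyte lists. In the double knockout, replicate 3 was lowest and replicate 2 highest in the interferon (6.58 and 7.37) and macrophage scores (8.65 and 9.59). The ApoE knockout did not show this. Its replicate 5 had the highest interferon (7.71) but the lowest macrophage score (9.06). Its replicate 3 had the lowest interferon (7.21) but the highest macrophage score (9.49).

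Class II antigen presentation genes were also lower, namely H2-Oa (1.73-fold), H2-Ob (1.44-fold), H2-Ab1 (1.67-fold) and H2-DMb2 (1.71-fold), 4 of 10 measured and 4 adjusted over the list alone (median -0.47, camera adjusted p = 4e-05, adjusted p = 0.51 with an estimated correlation). The score of the class II list did not pass after adjustment (exact permutation p = 0.016, adjusted p = 0.074). H2-Oa and H2-Ob encode the chains of H2-O, which is found mainly in B cells. The B cell score was also lower in the double knockout, as given above, but the 2 scores did not order the aortas alike. In the ApoE knockout, replicate 5 had the lowest B cell score (6.46) and the highest class II score (8.73). The H2-DMb2 call was lost without ApoE knockout replicate 1 (adjusted p = 0.058) or double knockout replicate 3 (adjusted p = 0.060).

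Some proliferation genes were lower as well. Mki67, the marker of dividing cells, was 2.32-fold lower (log2 SE 0.29, adjusted p = 0.0095), and the mitotic cyclins Ccnb2 and Ccna2 were 2.25-fold and 2.11-fold lower (SE 0.28 and 0.29). The replication licensing gene Mcm2 was 1.40-fold lower (SE 0.09). Of 23 cell cycle genes, 7 fell and none rose, also adjusted over the list alone (median -0.34, camera adjusted p = 1.5e-05, adjusted p = 0.51 with an estimated correlation). The cell cycle score did not pass (exact permutation p = 0.071, adjusted p = 0.18). T cell markers moved with it: ApoE knockout replicates 2, 3 and 4 had the highest cell cycle scores (7.55, 7.26 and 7.03) and the highest T cell scores (8.49, 8.17 and 7.98) of the 10 aortas.

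Genes known to respond to IL-17 moved in both directions. Of 27, 4 were higher and 4 lower in the double knockout, also adjusted over the list alone. Csf2, which encodes the growth factor GM-CSF, rose 1.54-fold from a mean of 5.65, below the level of the receptor genes (log2 SE 0.11, adjusted p = 0.0026), whereas S100a8 fell as above and Il1b was 2.50-fold lower (SE 0.31, adjusted p = 0.0090). The list's median was -0.02, and it did not pass (camera adjusted p = 0.24). In the IL-17 cytokine and receptor family, 4 of 16 genes were higher, also adjusted over the list alone, with Il23a at 1.48-fold but at the level of the receptor genes and not called after quantile normalization (adjusted p = 0.097). That list did not pass camera (median 0.16, adjusted p = 0.47), while its scores of 5.99 ± 0.05 and 6.15 ± 0.03 did not overlap (SD, n = 5, exact permutation p = 0.0079, adjusted p = 0.048). In the IL-17 cytokine and receptor family 6 of the 16 members lay at the level of the receptor genes, whose median change was 0.29, and the list's median was 0.04 after quantile normalization.

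Chemokine genes were lower in 6 of 27 and higher in 2. Ccl5, a T cell attractant, was 3.06-fold lower (SE 0.30, adjusted p = 0.0030), and the platelet chemokine genes Ppbp and Pf4 were 2.60-fold and 1.71-fold lower (SE 0.12 for each), while Cxcl11 was 1.58-fold higher at the level of the receptor genes. Adjusted over the list alone, 7 were lower and 2 higher (median -0.15, camera adjusted p = 0.0018, adjusted p = 0.51 with an estimated correlation). The list did not pass after quantile normalization without genes at the level of the receptor genes (adjusted p = 0.11). Ppbp and Pf4 also stand in the platelet list, of whose 17 genes 14 fell, and the macrophage list moved with the chemokine list (median -0.31), with double knockout replicate 3 lowest in both scores (7.32 for chemokines and 8.65 for macrophages).

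The list of endothelial activation and leukocyte adhesion had 5 of 19 genes lower and 2 higher, Madcam1 (1.38-fold, from a mean of 5.58 below the level of the receptor genes) and Alcam (1.30-fold), with the same counts adjusted over the list alone. Its median was -0.06 and its camera adjusted p 0.025, with adjusted p = 0.54 with an estimated correlation and 0.43 after quantile normalization. The endothelial markers were lower beside it (median -0.25, camera adjusted p = 0.0012, adjusted p = 0.51 with an estimated correlation), and double knockout replicates 1 and 3 were lowest in both scores (8.52 and 8.32 for the adhesion list, 9.32 and 9.35 for endothelial markers). The call of the adhesion list was also lost without ApoE knockout replicate 5 or double knockout replicates 1 or 3 (adjusted p from 0.058 to 0.082). In the list of p38 MAPK and AP-1 genes, Jund (1.36-fold, SE 0.07), the kinase target Atf2 (1.23-fold, SE 0.06), Mapk12 and Dusp1 were lower out of 21, 2 of them adjusted over the list alone (median -0.12, camera adjusted p = 0.00050). It had adjusted p = 0.51 with an estimated correlation and 0.067 after quantile normalization, which also ended the calls of Mapk12 and Dusp1. These calls were lost as well without any one of 6 aortas for Mapk12 (adjusted p from 0.073 to 0.078) and of 8 for Dusp1 (0.064 to 0.096).

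Some genes of the extracellular matrix and of contractile smooth muscle were higher in the double knockout, where leukocyte and blood cell markers were lower. This did not hold for all cells of the wall, since the endothelial list was lower (median -0.25) and the adventitial fibroblast list did not pass camera (adjusted p = 0.87). Of 23 extracellular matrix genes, 11 rose and none fell, among them tenascin C, Tnc (1.89-fold, log2 SE 0.12), the collagens Col15a1 (1.72-fold, SE 0.11) and Col5a1 (log2 change 0.59, SE 0.08), and lumican, Lum (1.36-fold, SE 0.07). Of 15 genes of contractile smooth muscle, 7 rose and none fell, including the potassium channel subunit Kcnmb1 (1.39-fold, SE 0.09), tropomyosin 2, Tpm2 (1.32-fold, SE 0.09), the integrin Itga8 (1.28-fold, SE 0.09) and smooth muscle myosin, Myh11 (1.31-fold, SE 0.11). The Myh11 call was lost when arrays were centred on their median (adjusted p = 0.056) and without any one of 4 aortas, ApoE knockout replicates 2, 3 and 4 and double knockout replicate 3 (adjusted p from 0.053 to 0.060).

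Adjusted over the list alone, 13 matrix genes and 8 smooth muscle genes were higher. The medians were 0.34 for matrix genes (camera adjusted p = 0.0014, adjusted p = 0.51 with an estimated correlation) and 0.28 for smooth muscle genes (camera adjusted p = 0.014, adjusted p = 0.54 with an estimated correlation). The matrix score rose from 10.22 ± 0.09 to 10.55 ± 0.16 (SD, n = 5, exact permutation p = 0.0079, adjusted p = 0.048), and the smooth muscle scores were 11.04 ± 0.20 and 11.33 ± 0.04 (exact permutation p = 0.024, adjusted p = 0.10). Within the ApoE knockout, replicate 2 had the lowest smooth muscle score (10.78) and the highest T cell score (8.49). Replicate 5 had the highest smooth muscle score (11.33) and the lowest T cell score (6.73). The double knockout did not show this inverse order. Its replicates 5 and 1 were highest in both the smooth muscle (11.37 and 11.35) and the T cell scores (6.81 and 7.17). Both medians were of similar size after quantile normalization, at 0.38 and 0.29.

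Heat shock genes rose in 8 of 14 cases with no gene lower, and adjusted over the list alone 9 were higher and 1 lower. Beside Hspa1a and Hspa1b, the co-chaperone gene Dnajb1 rose 1.85-fold (SE 0.15) and Hsp90aa1 1.48-fold (SE 0.10). The median was 0.44 (camera adjusted p = 0.0082, adjusted p = 0.54 with an estimated correlation), and the heat shock score did not pass after adjustment (exact permutation p = 0.016, adjusted p = 0.074). Cardiac muscle genes were higher in 8 of 15, also adjusted over the list alone, such as the calcium release channel Ryr2 (1.78-fold, SE 0.15) and phospholamban, Pln (1.83-fold, SE 0.16), with a median of 0.50 (camera adjusted p = 0.0031, adjusted p = 0.51 with an estimated correlation). In that list 4 members lay at the level of the receptor genes, whose median change was 0.29, and the median was 0.33 after quantile normalization.

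The lists of oxidative phosphorylation, fatty acid synthesis and fatty acid oxidation were lower, with few single genes past the threshold. Of 35 oxidative phosphorylation genes 3 fell, Atp5h (1.39-fold), Ndufb9 (log2 change -0.59) and Uqcrfs1 (1.49-fold), 2 adjusted over the list alone (median -0.21, camera adjusted p = 5.7e-06, adjusted p = 0.54 with an estimated correlation). The Atp5h call was lost with the mean of its probe sets (adjusted p = 0.47), and that of Uqcrfs1 without any one of ApoE knockout replicates 3 and 4 and double knockout replicates 4 and 5 (adjusted p from 0.055 to 0.064). Thrsp, a regulator of lipogenesis, was 2.09-fold lower (SE 0.32, adjusted p = 0.028) as the only called gene of 19 in fatty acid and triglyceride synthesis, a call lost without any one of 5 aortas, ApoE knockout replicates 1, 3 and 4 and double knockout replicates 4 and 5 (adjusted p from 0.054 to 0.063). None passed adjusted over the list alone (median -0.50, camera adjusted p = 0.00033, adjusted p = 0.51 with an estimated correlation). None of 19 fatty acid oxidation genes passed, in either adjustment (median -0.28, camera adjusted p = 0.00073, adjusted p = 0.54 with an estimated correlation).

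White adipocyte markers moved the same way as the lipid lists (median -0.33, none of 16 past the threshold or adjusted over the list alone, camera adjusted p = 0.013, adjusted p = 0.54 with an estimated correlation). Their mean level was 9.11 ± 0.59 in the ApoE knockout and 8.81 ± 0.43 in the double knockout (SD, n = 5, exact permutation p = 0.37). After quantile normalization the lists of fatty acid synthesis, fatty acid oxidation and white adipocytes no longer passed, with adjusted p-values of 0.067, 0.074 and 0.27. The white adipocyte list also did not pass without ApoE knockout replicate 1 (adjusted p = 0.14) or double knockout replicate 5 (adjusted p = 0.056).

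A further 7 lists were lower by camera with the preset correlation and no longer passed after quantile normalization. Among macrophage genes, the scavenger receptor Cd163 (1.76-fold, SE 0.10) and F13a1 (1.35-fold, SE 0.12) fell out of 15, also adjusted over the list alone (median -0.31, camera adjusted p = 0.00072, adjusted p = 0.51 with an estimated correlation). The F13a1 call was lost without ApoE knockout replicate 3 (adjusted p = 0.051). Among endothelial genes, 3 of 15 fell, Tek, Pecam1 and Eng (1.21-fold to 1.38-fold), and Flt1 rose 1.21-fold, also adjusted over the list alone (median -0.25, camera adjusted p = 0.0012, adjusted p = 0.51 with an estimated correlation). Each of these 4 calls was lost without any one of several aortas, 4 for Tek, 5 for Flt1 and 7 each for Pecam1 and Eng (highest adjusted p from 0.056 to 0.096). Among ribosomal proteins, Rpl14, Rps9 and Rplp0 fell and Rps23 rose out of 28, also adjusted over the list alone (median -0.08, camera adjusted p = 0.0018, adjusted p = 0.51 with an estimated correlation). The direction of Rplp0 turned with the mean of its probe sets (0.03). The calls of Rps9, Rplp0 and Rps23 were lost after quantile normalization (adjusted p = 0.050, 0.055 and 0.13).

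Among glycolysis genes, Pfkp rose 1.33-fold and Slc16a3, Pfkfb3 and Pfkl fell out of 15, 1 each way adjusted over the list alone (median -0.16, camera adjusted p = 0.013, adjusted p = 0.51 with an estimated correlation). The calls of Slc16a3, Pfkfb3 and Pfkl were lost without any one of 3, 8 and 7 aortas (highest adjusted p 0.063, 0.089 and 0.10). Among cholesterol synthesis genes, Fdps was 1.40-fold lower as the only call among 16, also adjusted over the list alone (median -0.15, camera adjusted p = 0.015, adjusted p = 0.51 with an estimated correlation). Of 17 foam cell genes, Olr1, the oxidized LDL receptor LOX-1, rose 2.10-fold from a mean of 5.38, below the level of the receptor genes (SE 0.21), and Nr1h3, the oxysterol receptor LXR alpha, fell 1.32-fold (SE 0.11), also adjusted over the list alone (median -0.21, camera adjusted p = 0.028, adjusted p = 0.54 with an estimated correlation). Of 17 oxidative stress genes, Gclm, a subunit of the enzyme that limits glutathione synthesis, fell 2.49-fold (SE 0.08, adjusted p = 4e-06) and Cat 1.41-fold. Gpx2, at the level of the receptor genes, and Gstm1 rose, and the counts of 2 lower and 2 higher were the same adjusted over the list alone (median -0.08, camera adjusted p = 0.042, adjusted p = 0.51 with an estimated correlation). The Gstm1 call was lost without any one of 6 aortas (adjusted p from 0.052 to 0.062). Without ApoE knockout replicate 1 the glycolysis and cholesterol lists did not pass (adjusted p = 0.066 for both), and leaving out any one of 4 aortas ended the call of the foam cell list (highest adjusted p 0.15) and of the oxidative stress list (0.088).

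The other 15 lists tested did not pass camera. Among their genes, Atf4, the stress-induced transcription factor, rose 1.94-fold (SE 0.09, adjusted p = 7e-05), Nr4a3 rose 1.92-fold (SE 0.14) and Klf2, a flow-responsive endothelial factor, fell (log2 change -0.59, SE 0.16). Il1rn, the interleukin 1 receptor antagonist, rose 1.76-fold (SE 0.21), Mmp14 rose 1.45-fold and Adamts4 1.53-fold. Camera adjusted p-values were 0.092 for immediate early genes (1 higher and 2 lower of 21), 0.11 for the inflammasome list (2 and 2 of 17), 0.067 for complement (1 and 1 of 17), 0.14 for circadian clock genes (3 and 1 of 16), 0.80 for the unfolded protein response (2 higher of 17) and 0.54 for matrix proteases (3 and 1 of 21). Mitochondrially encoded genes had no call among 7 (0.28).

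Of the cell type lists without a call, the adjusted p-values were 0.87 for adventitial fibroblasts (3 higher and 1 lower of 14), 0.085 for plasma cells (1 lower of 10), 0.057 for dendritic cells (1 higher and 2 lower of 11) and 0.057 for brown adipocytes (1 higher of 14). They were 0.23 for skeletal muscle (4 higher of 18), 0.88 for Schwann cells (4 higher and 3 lower of 12), 0.32 for mesothelium (2 higher of 12) and 0.16 for chondrocytes (6 higher of 14). Adjusted over the list alone, the counts of higher and lower genes were 1 and 1 for immediate early genes, 2 and 2 for the inflammasome, 0 and 0 for complement, 3 and 0 for the clock, 1 and 0 for the unfolded protein response and 3 and 1 for matrix proteases. In the same terms they were 0 and 0 for mitochondrially encoded genes, 3 and 1 for fibroblasts, 0 and 1 for plasma cells, 0 and 1 for dendritic cells, 1 and 0 for brown adipocytes, 3 and 0 for skeletal muscle, 6 and 3 for Schwann cells, 2 and 0 for mesothelium and 6 and 0 for chondrocytes. Matrix proteases and fibroblasts had a median and mean above 0 and a camera direction below it. Leaving out 1 aorta brought 7 of these lists past the threshold, skeletal muscle without ApoE knockout replicate 2 (adjusted p = 0.0046), brown adipocytes without any one of 4 aortas (lowest 0.0022), and immediate early, complement, inflammasome, plasma and dendritic cell lists without 1 or 2 aortas (0.0081 to 0.049).

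In all, 25 of 42 lists passed camera with the preset correlation, 4 higher and 21 lower. None passed with an estimated correlation, where 2 had an unadjusted p under 0.05, 9 passed with fry and 7 by exact permutation of the list scores, a test chosen after the data were seen. Those 7 were the B cell, neutrophil and mast cell lists, which were lower, and the matrix, cardiac muscle, chondrocyte and IL-17 family lists, which were higher. List scores are not set against other genes, so a higher background can raise them. The chondrocyte list had a median of 0.30, beside 0.29 for the receptor genes, with 3 of its 14 members at their level. Neither it nor the IL-17 family list passed camera (adjusted p = 0.16 and 0.47). Other splits of the 10 arrays also called many lists, up to 27, so the number of called lists cannot be set apart from chance, whereas the highest gene count in any other split drawn was 2.

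Genes near Il17a on chromosome 1 were examined because a deletion made in another strain brings flanking DNA with it. Of 69 measured genes among the 100 on each side, 26 (37.7%) changed, 23 of them higher and 3 lower, against 30.3% of all other genes (Fisher's exact test, two-sided, p = 0.19). The most clearly changed were Pi15, a protease inhibitor (1.91-fold higher, SE 0.11, adjusted p = 0.00031), Tfap2d (1.61-fold higher, at the level of the receptor genes), Tram2 (1.33-fold higher), Ogfrl1 (1.52-fold lower) and Stau2 (1.44-fold higher), beside Il17f itself. The same window around Apoe, deleted in both groups, held 30 changed genes of 93 (32.3%, Fisher's exact test, two-sided, p = 0.65).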

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

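The tests of blood RNA, of normalization for the blood genes and of the dim genes were chosen only after the results were seen. For the region around Il17a the comparison itself was fixed before the data were examined, and only the ratio that would decide about flanking DNA was set afterwards.

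Several values stood apart from the other 4 arrays of their group by a gap of over 0.71 of the group's range. Of 146 group values examined 7 did so, where chance gives about 1 in 20. In the double knockout, replicate 2 had the highest Apol11b (6.45, the others 5.45 to 5.69), the highest Hbq1a (6.47, the others 5.51 to 5.76) and the highest cardiac muscle score (6.95, the others 6.41 to 6.51). In the ApoE knockout, replicate 2 had the highest Slc4a1 (10.78, the others 10.12 to 10.28) and the highest skeletal muscle score (6.37, the others 5.61 to 5.75), replicate 4 the highest cardiac muscle score (6.31, the others 5.89 to 5.96) and replicate 5 the highest matrix score (10.37, the others 10.16 to 10.21). Outside the genes tested, 347 of 1814 probe sets with several genes and 3323 of 16010 unnamed probe sets changed, 278 and 2974 of them higher.

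The lists of red cell, platelet, neutrophil, B cell and T cell genes were lower in the double knockout. The red cell list's median of -0.48 was -0.61 after quantile normalization and -0.84 when the genes at the receptor level, 3 of its 32, were also left out. Because that list was put together after its genes had been seen, this does not decide about array background and normalization. The B cell, T cell and neutrophil lists, fixed before, still passed camera with the preset correlation after quantile normalization (adjusted p = 3.9e-08, 5.2e-05 and 0.00045). More blood in the ApoE knockout aortas is a candidate explanation, and the median was below 0 in 5 of 5 lists, among them Ppbp at 12.70 and Slc25a37 at 12.50 in the ApoE knockout. That cannot be told apart from an effect of genotype on blood cells or leukocytes in the wall, which would lower the same lists, and the red cell and platelet lists were put together after their genes had been seen, with 2 of 17 platelet, 5 of 15 neutrophil and 1 of 12 T cell genes also in another list. Mast cells do not circulate as mature cells, and their list fell too (median -0.71), which blood alone leaves unaccounted for. The blood cell scores also did not all vary together among the ApoE knockout aortas. Replicate 1 had the lowest red cell score (7.62) but the highest platelet (9.03) and B cell scores (7.17), while replicate 2 had the highest red cell (7.94) and T cell scores (8.49). This variation within the group is not accounted for by 1 shared amount of blood.

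Dim genes were higher in the double knockout. A true rise of these transcripts as a set, beyond the background, is argued against. The other genes of the lowest 40% rose by less than the receptor genes (difference of medians -0.044). This comparison of medians does not decide about single dim genes, some of which rose by more, such as Cypt14 (log2 change 1.62). Higher array background in the double knockout arrays, which may come from a separate batch, remains open: receptor genes, which the aorta is not known to use, had a median of 0.29.

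Chance can be excluded for the number of changed genes: of 100 of the 126 distinct splits of the arrays, 1, the real one, gave 6721, and the highest other gave 2. It cannot be excluded for the number of called lists, where 6 of the 100 splits, the real one included, gave at least 25 and the highest other gave 27. The share of changed genes next to Il17a was 1.24 times that of all other genes, which does not decide whether flanking DNA of the other strain added to it.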

How the results depend on the processing

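The alternatives chosen after the data were seen were the 2 settings without genes at the receptor level, the 2 without blood cell genes and the exact test of list scores. The count of 6721 genes ran from 4743 to 8986 under median centring, mean probe sets, another prior, array weights, covariates, adjusted p under 0.1, Welch's test and removal of blood cell genes, and from 5056 to 7022 with each array left out. It was 3419 without the lowest 40% of genes, 3973 without genes at the receptor level, 4461 after quantile normalization (3382 shared with the main calls), 3663 with both of the last, 2970 at adjusted p under 0.01, 1640 with an added 1.5-fold threshold and 1729 at unadjusted p under 0.05 with 1.5-fold. Fewer genes tested or a stricter threshold accounts for part of this by construction, and the cause of the change with quantile normalization was not tested. The 25 lists ran from 22 to 29 with each array left out, and were 0 with an estimated correlation, 9 with fry (7 shared), 13 after quantile normalization, 12 after it without genes at the receptor level and 7 by exact permutation of list scores (5 shared), and the cause was not tested. The share near Il17a ran from 27.3% to 41.9% and passed no test. With each array left out, the change of Il17a ran from 0.18 to 0.30 and that of Apoe from 0.60 to 0.71. Low signal over background limits what can be said of the 8002 genes below the receptor level in both groups.

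With the replicate number as a block, 6594 genes and 28 lists were called, the 3 more being brown adipocytes, plasma cells and dendritic cells, and of the named genes 13 gained and 4 lost a call. The numbers were not taken to pair the arrays, since the labels give no pairing and 3 of 5 pairs, not all, had a correlation over 0.1 (from -0.13 to 0.26 across genes). In each group 3 of 5 arrays matched best with their own number, a hint from the data that leaves some shared structure open. Under the replicate block the Schwann cell list turned direction in camera (0.0052).

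Other directions that turned belonged to uncalled results, Rplp0 excepted, and the cause was not tested. Il17a went to -0.019 after quantile normalization and Rplp0 to 0.029 with the mean of probe sets. The following are mean changes of a list minus that of other genes, where the list test gave the opposite direction to the main one. Matrix proteases had -0.081 with fry, 0.0083 without the lowest 40%, 0.017 after quantile normalization, -0.0072 without genes at the receptor level, 0.031 with both and -0.000185 without blood cell genes. Fibroblasts had -0.051 with fry, 0.052 without the lowest 40%, 0.11 after quantile normalization, -0.034 with array weights, 0.037 without genes at the receptor level and 0.13 with both. With each array left out they ran from -0.083 to -0.0065 and turned without ApoE knockout replicate 5 (-0.035) or double knockout replicate 1. The unfolded protein response had 0.028 on ranks and -0.013 with the adipocyte covariate, and ran from -0.023 to 0.075 with each array left out, turning without ApoE knockout replicate 1 (0.0074) or double knockout replicate 5. Mitochondrially encoded genes had 0.050 after quantile normalization and 0.068 without genes at the receptor level as well, where immediate early genes had 0.023 and clock genes 0.033. IL-17 response genes had -0.20 with fry and Schwann cell genes -0.021 with the mean of probe sets.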

Other observations

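The tests of the platelet, red cell and clock arm lists and scores were chosen only after the data were seen (for the clock gap after quantile normalization, before its own value was known), as were the genes named here other than Nfil3 and Clock, while the adjusted p-values of single genes come from the fit fixed before.

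Most platelet genes were lower in the double knockout aortas. Of 17 measured, 14 fell, 1, the integrin Itgb3 (1.34-fold), rose and 2, F2rl3 (log2 change 0.21) and Rab27b (-0.03), did not pass. The von Willebrand receptor subunit Gp9 was 4.41-fold lower (11.21 ± 0.23 against 9.07 ± 0.46, mean log2 value ± SD, n = 5), the receptor Clec1b 4.25-fold (SE 0.28 on the log2 scale), platelet tubulin, Tubb1, 3.83-fold (SE 0.18) and the collagen receptor Gp6 2.49-fold (SE 0.13). The list's median was -1.04 and its camera adjusted p 2.7e-14, over the 4 lists added after the data were seen. With an estimated correlation it had adjusted p = 0.023, over the same 4 lists. These adjusted values cannot be set beside those of the fixed lists. The platelet scores, 8.81 ± 0.19 and 7.78 ± 0.18, did not overlap (exact permutation p = 0.0079). The platelet list was put together after its genes had been seen, so its p-values do not test the decrease independently.

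Of 32 red cell genes, 16 were lower and 1, Trim58 (1.39-fold), higher. Fech, the last enzyme of heme synthesis, was 5.36-fold lower with the smallest adjusted p of all genes (5.8e-07), and Trim10, Tspo2 and Rhag were at least 4.11-fold, 4.00-fold and 3.06-fold lower, to means of 5.71, 5.72 and 4.90 below the level of the receptor genes. The erythroid transcription factors Gata1, Klf1 and Tal1, which act in precursors, did not pass (log2 changes -0.29, 0.11 and -0.01), Gata1 and Klf1 at the level of the receptor genes. The list's median was -0.48 and its camera adjusted p 2.5e-17, with adjusted p = 0.018 with an estimated correlation. Both adjustments cover only the lists added after the data were seen, so they cannot be set beside those of the fixed lists. The red cell list was put together after its genes had been seen, so these p-values do not test the decrease independently. The gap between the red cell and platelet scores differed by 0.07 between groups (exact permutation p = 0.66).

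Among clock genes, Npas2 (1.98-fold, adjusted p = 0.013), Nfil3 (1.61-fold, adjusted p = 0.0045) and Clock (1.34-fold, adjusted p = 0.012) rose, and Hlf fell 1.47-fold (adjusted p = 0.048), while Dbp (log2 change -0.64, adjusted p = 0.071) and Arntl (0.51, adjusted p = 0.16) did not pass. The mean of 5 genes that peak with Arntl differed (exact permutation p = 0.016, adjusted p = 0.029 over 24 measures), that of 8 that peak with Dbp did not pass (9.04 ± 0.16 against 8.73 ± 0.41, SD, n = 5, exact permutation p = 0.17, adjusted p = 0.21), while camera gave the opposite calls (adjusted p = 0.083 and 0.011), and each had adjusted p = 0.33 with an estimated correlation. The first mean minus the other was -1.14 ± 0.26 in the ApoE knockout and -0.31 ± 0.71 in the double knockout, a gap of 0.83 (exact permutation p = 0.032, adjusted p = 0.048), with double knockout replicate 5 (-1.13) within the ApoE knockout range and replicate 1 (-0.76) just above its highest value (-0.78). A shift of array background or normalization that depends on level alone is argued against by a gap of 0.79 after quantile normalization. Batch effects that differ from gene to gene are not removed by it, so it cannot decide about them. Another time of day at collection may be a cause, as a hypothesis, but Nr1d1 (0.16) and Cry1 (0.00) did not move with their arms, and time of day and genotype cannot be told apart because collection times are not given.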
